A study of Mus musculus with 22 samples.

How the data were processed

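Gene expression was measured by RNA sequencing in 22 libraries of sorted mouse CD8+ T cells in 10 groups. Per the labels, cells were sorted into TCL lysis buffer, RNA was captured on RNAClean XP beads and libraries were made with the PrepX RNA-seq kit; the authors named STAR, featureCounts and DESeq without versions, and the genome build mm10. The label part "V" was read as VHL-deficient, and Vhl reads matched that reading in all 22 libraries. All libraries lay on 1 plate: column 1 held the Trm and nonTrm sorts, column 2 the day 7 spleen and unsplit tumor cells and column 3 the day 11 cells. Genotype, Trm against nonTrm and tumor against spleen were therefore compared within 1 column, while day, and sorted against unsplit cells, are confounded with column.

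The table deposited by the authors holds a signal per gene and library, 46297 rows for 46252 symbols by 22 columns, while its header states 55 samples. The deposited signal is a read count divided by 1 size factor per library, plus 1: every value minus 1 was a whole multiple of 1 step per library in 100% of values (tolerance 0.01 reads, largest deviation 0.000282). The offset was removed and read counts were recovered from the step. The size factors were 0.876 to 0.943 times those recomputed by the median of ratios, a nearly constant ratio, and were kept. Of the 43 duplicated symbols (88 rows), the row with the highest mean kept the symbol and the others were kept under separate names, and 26 names look like dates made by a spreadsheet. Of all rows, 40936 had a read in 1 library or more.

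Genes with a scaled count of at least 10 in at least 2 libraries were tested, 14327 in all. Limma 3.58.1 in R 4.3.3 was run on log2(scaled count + 1) in 1 fit of 10 group means over all 22 libraries (12 residual degrees of freedom), with eBayes(trend=TRUE) and Benjamini-Hochberg adjustment over the tested genes; a gene was called at an adjusted p under 0.05. There were 14 comparisons: genotype in 5 settings, Trm against nonTrm and tumor against spleen and day 11 against day 7 in each genotype, and the interactions of genotype with subset, tissue and day. Tests are two-sided. Group levels are the mean and SD of scaled counts. A fold against a group with 0 reads is a lower bound against a floor of 3 reads per library; with 1 to 3 reads, the ratio is given with its exact 95% counting interval. Floors and intervals cover counting error only.

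The groups, comparisons, filter, threshold, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The 34 lists (536 entries) cover HIF targets (glycolysis and glucose uptake; others), oxygen sensing, oxidative phosphorylation, the TCA cycle and pyruvate dehydrogenase, fatty acid oxidation, cholesterol synthesis, amino acid transport and stress response, tissue residency, circulating memory, cytotoxic molecules, inhibitory receptors and exhaustion, stem-like and memory genes, effector transcription factors, costimulatory receptors, chemokines and their receptors, proliferation, type I interferon, TGF-beta, immediate early genes and the unfolded protein response. They also cover markers of melanoma, macrophages and monocytes, neutrophils, dendritic, B, NK and CD4 T cells, fibroblasts and endothelium, erythroid cells and T cells, 2 RNA-quality lists and sex-linked genes. Each was tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison; lists with 1 measured gene were not tested.

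Named genes were Vhl; the fixed genes Slc2a1, Pdk1, Ldha, Pgk1, Vegfa, Hif1a, Gzmb, Ifng, Pdcd1, Tcf7, Itgae and Cd69 for genotype, and a set that includes Itgae, Cd69, Cxcr6, Klf2, S1pr1 and Klrg1 for Trm against nonTrm; the 10 (day 11 tumor, unsplit day 7 tumor, Trm against nonTrm) or 5 (other comparisons) largest fold changes per direction among called genes whose groups did not overlap and whose mean log2 level was above the median of 6.08, without unnamed gene models, receptor segments, Y-linked genes and Xist; and up to 4 called members per list with the smallest adjusted p, or else up to 2 with the highest level. Other called members are given as counts or in short.

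Alternatives were a further TMM scaling, other filters, pseudocounts of 0.5 and 5, eBayes without trend, library weights, a replicate block, a fit of only the groups compared, and leaving out each library in turn. Where that left 1 library in a group, it was assumed to vary like the other groups. Alternatives added after seeing the data were voom on the recovered reads, a fit without VHL-deficient nonTrm replicate 2, scaling without ribosomal and mitochondrial genes, a crossed replicate block and recomputed size factors. The test was checked on simulated data. Positions are from GENCODE M21 on mm10, which gave 1 position for 13925 tested genes (97.2%). Tables and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.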

Results

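RNA sequencing measured gene expression in 22 libraries of mouse CD8+ T cells. The cells were P14 T cells of the C57BL/6 strain, whose transgenic receptor recognises a peptide of lymphocytic choriomeningitis virus. They came from spleen or from tumor, on day 7 or day 11, and were either wild type (WT) or deficient in VHL. The VHL protein is the part of a ubiquitin ligase that binds hydroxylated hypoxia-inducible factor (HIF) alpha subunits and marks them for degradation. The libraries fall into 10 groups. Day 11 tumor has 3 libraries of each genotype, and the other 8 groups have 2 libraries each: day 7 spleen, unsplit day 7 tumor, and day 7 tumor cells sorted as Trm (tissue-resident memory) or nonTrm, in each genotype. The series labels give 5 mice for each biological replicate. The tumor, the event that day 0 marks and the markers of the Trm sort are not given in the sources used here.

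Each library held between 3375558 and 10211060 reads assigned to genes. The ribosomal RNA gene CT010467.1 took 26.9% to 45.7% of them, and the mitochondrial genome took 2.89% to 12.1%. Outside both, 1739784 to 6053474 reads remained per library, and 17139 to 25922 genes had a read. All levels below are size-factor scaled counts, given as mean ± SD, and 1 read corresponds to 0.684 to 2.73 scaled counts depending on the library. Log2 fold changes (log2FC) are differences of log2(scaled count + 1). The p-values measure the spread between these libraries.

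Vhl itself (mm10 chromosome 6, 113623959 to 113631633, 3 exons in the GENCODE M21 annotation) had 0 to 32 reads in each VHL-deficient library and 60 to 280 reads in each WT library. Its level was 11.2 ± 6.70 against 144 ± 19.0, log2FC -3.77, adjusted p = 0.00109 in day 11 tumor (n = 3 each). In unsplit day 7 tumor it was 3.43 ± 2.94 against 159 ± 25.2, log2FC -5.34, adjusted p = 5.22e-04 (n = 2 each). Spleen gave 14.6 ± 7.84 against 124 ± 18.9, log2FC -3.10, adjusted p = 0.0361, Trm cells 5.05 ± 7.14 against 143 ± 45.6, log2FC -5.40, adjusted p = 2.52e-04, and nonTrm cells 16.4 ± 7.76 against 181 ± 41.9, log2FC -3.44, adjusted p = 0.0241 (n = 2 each). Vhl was called lower in all 5 genotype comparisons.

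**Figure D1:**
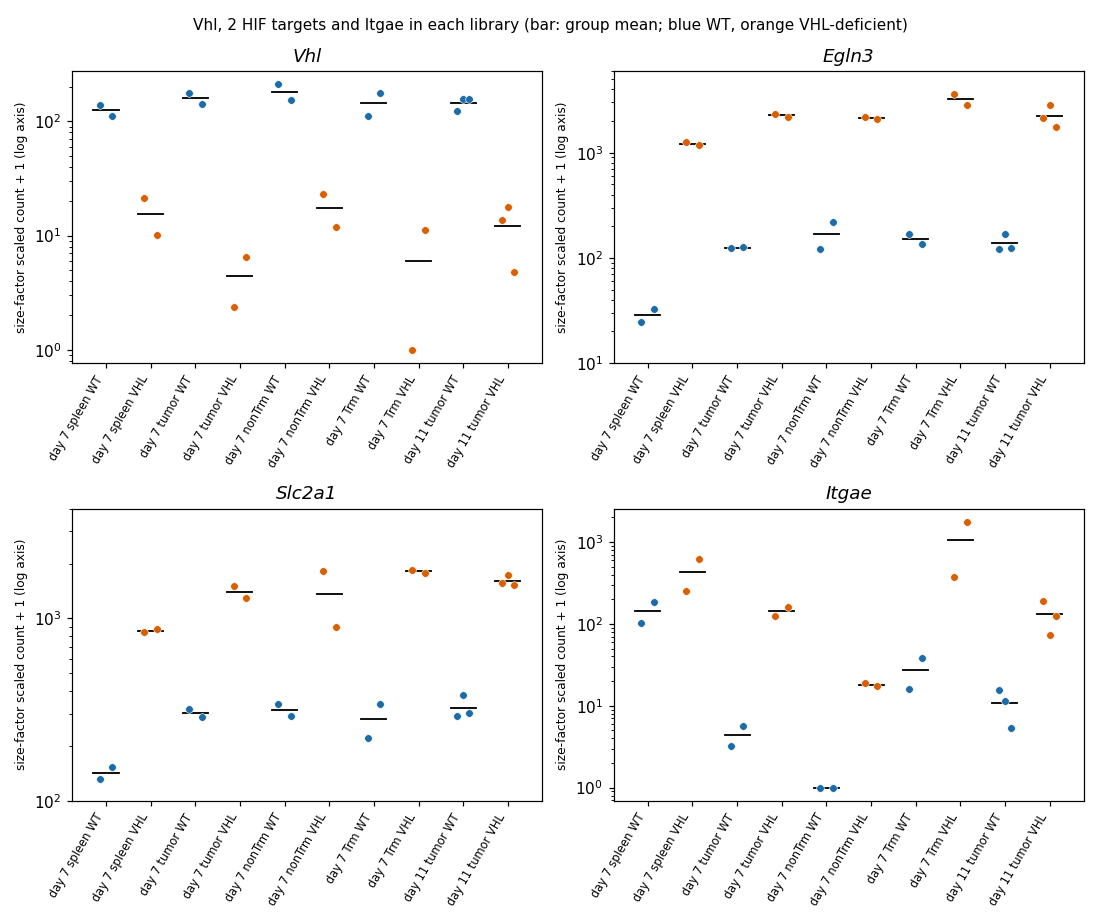
Levels of Vhl, the HIF targets Egln3 and Slc2a1, and Itgae in each of the 22 libraries, as size-factor scaled count plus 1 on a log axis, with 1 point per library and a bar at each group mean. VHL-deficient libraries (orange) lie below WT libraries (blue) for Vhl and above them for Egln3 and Slc2a1 in each of the 5 pairs of groups.

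The first principal component of the tested genes held 26.4% of the variance and parted the 4 spleen libraries, at 97.6 to 114, from the 18 tumor libraries, at -48.4 to 15.4. The second held 19.6% and parted the genotypes: VHL-deficient tumor libraries lay at 35.0 to 70.8 and WT tumor libraries at -68.7 to -27.1. On the third component, with 12.0%, replicate 2 of the VHL-deficient nonTrm cells stood alone at -133. That library also had the highest share of ribosomal RNA reads, 45.7%, and 34360 scaled counts of the nuclear RNA Malat1, against 4839 to 15030 in the other 21 libraries.

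**Figure D2:**
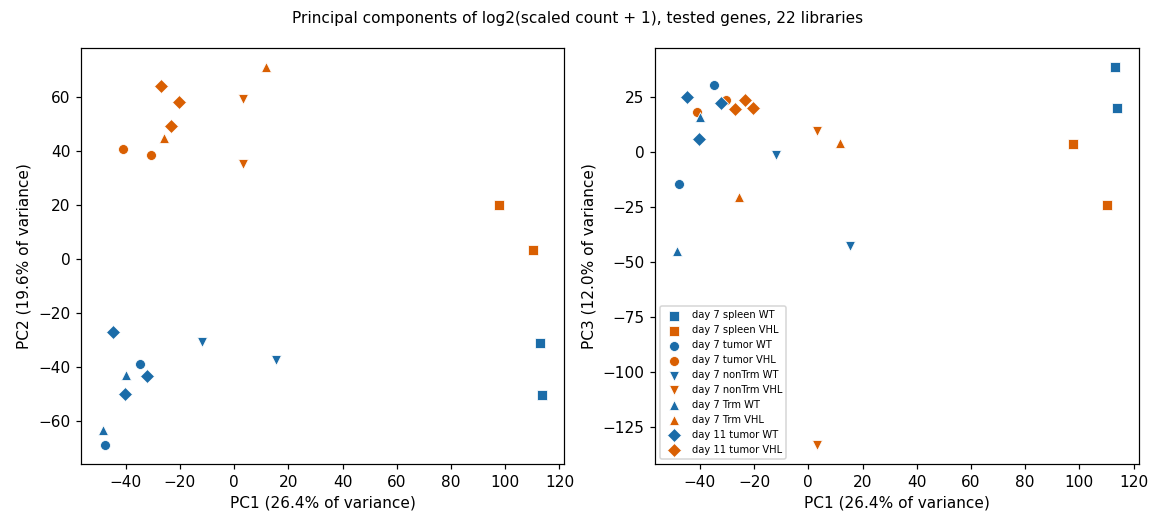
Principal components 1, 2 and 3 of log2(scaled count + 1) over the tested genes, with 1 point per library, colour for genotype and shape for tissue, day and subset. Tissue separates along component 1 (26.4% of variance) and genotype along component 2 (19.6%), and 1 VHL-deficient nonTrm library lies at -133 on component 3.

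The comparison of VHL-deficient with WT cells in day 11 tumor asked what loss of VHL changed among tumor-infiltrating CD8+ T cells. Genes that rose included the HIF targets P4ha2, Egln3 and Bnip3. Mgarp, a mitochondrial protein, stood at 764 ± 104 against 13.7 ± 5.30, log2FC 5.75, adjusted p = 8.42e-08 (n = 3 each). P4ha2, which hydroxylates prolines of collagen, stood at 846 ± 78.4 against 25.1 ± 5.75, log2FC 5.04, adjusted p = 4.48e-10. Egln3, a prolyl hydroxylase that acts on HIF, stood at 2250 ± 564 against 136 ± 26.0, log2FC 4.02, adjusted p = 1.23e-09. The mitophagy receptor Bnip3 was at 3076 ± 308 against 207 ± 63.9, log2FC 3.92, adjusted p = 2.66e-08. St6gal1, a sialyltransferase (1569 against 38.6, log2FC 5.32), the growth factor receptor Igf1r (512 against 16.7, log2FC 4.90), Sema6d (958 against 48.2, log2FC 4.59), Rgs11 (1431 against 64.8, log2FC 4.44), the glycogen phosphorylase Pygl (1479 against 104, log2FC 4.05) and the class II MHC gene H2-Ab1 (1574 against 126, log2FC 3.80) rose as well. The muscle-type enolase Eno3 fell (37.4 ± 4.31 against 239 ± 42.6, log2FC -2.64, adjusted p = 6.82e-06). So did Cdca8, Cks1b, Birc5, Ube2c, Stmn1, Ccna2, Cdca5, Spc25 and Melk, genes known from cell division, with log2FC from -2.46 to -2.22. In mm10, Mgarp lies on chromosome 3, 51388412 to 51396738, P4ha2 on chromosome 11, 54100095 to 54131665, Egln3 on chromosome 12, 54178981 to 54203860, H2-Ab1 on chromosome 17, 34257689 to 34269419 and Eno3 on chromosome 11, 70657202 to 70662513.

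In all, 641 of 14327 genes rose and 343 fell in day 11 tumor, 984 together. The count was 419 without VHL-deficient replicate 2, 482 without WT replicate 3, 501 without VHL-deficient replicate 1 and 578 without WT replicate 1. It was 1549 without VHL-deficient nonTrm replicate 2, a library outside the comparison that enters the shared variance.

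HIF targets rose as a group in day 11 tumor. Among targets in glycolysis and glucose uptake, 18 of 21 genes rose and 0 fell (19 and 0 adjusted over the list alone). The list had a median log2FC of 1.65 and camera adjusted p = 4.16e-18 (0.00177 with an estimated correlation). They included the glucose transporter Slc2a1 (1606 ± 104 against 324 ± 48.8, log2FC 2.32, adjusted p = 1.73e-06), the lactate transporter Slc16a3 (3698 against 591, log2FC 2.68), Aldoc (1713 against 192, log2FC 3.23), the hexokinase Hk2 (986 against 102, log2FC 3.31), Pgk1 (3326 against 1068, log2FC 1.65) and Pdk1, which inhibits pyruvate dehydrogenase (1260 against 333, log2FC 1.92). Ldha, lactate dehydrogenase, had 25350 ± 1649 against 13510 ± 3613, log2FC 0.94, adjusted p = 0.0552 and was not called. Among other HIF targets, 20 of 26 genes rose and 0 fell (23 and 0 adjusted over the list alone). The members had a median log2FC of 1.93 and camera adjusted p = 2.07e-25 (1.09e-04 with an estimated correlation). Ndrg1 (4015 against 487, log2FC 3.04) and the angiogenic factor Vegfa (75.9 ± 26.1 against 5.62 ± 2.24, log2FC 3.54, adjusted p = 4.28e-05) were among them. Of the oxygen-sensing genes, 3 of 12 genes rose and 0 fell (3 and 1 adjusted over the list alone). The risen ones were Egln3, Egln1 (255 against 74.9, log2FC 1.78) and Hif3a (29.8 against 1.44, log2FC 4.06). The list as a whole had a camera adjusted p = 0.143. Hif1a itself had 1586 ± 211 against 2427 ± 189, log2FC -0.62, adjusted p = 0.123.

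Respiratory genes lay lower in the same cells. In oxidative phosphorylation, 0 of 31 genes rose and 4 fell (0 and 6 adjusted over the list alone). As a set, these had a median log2FC of -0.66 and camera adjusted p = 2.91e-08 (0.314 with an estimated correlation). The called ones were Ndufa4 (111 against 323, log2FC -1.51), Cox5a (437 against 1038, log2FC -1.24), Cyc1 (548 against 1009, log2FC -0.86) and the ATP synthase subunit Atp5b (4655 against 8495, log2FC -0.85). Idh3a (-0.88) and Fh1 (-0.77) fell among 16 genes of the TCA cycle and pyruvate dehydrogenase (0 rose, 2 fell, 3 fell adjusted over the list alone, median log2FC -0.35, camera adjusted p = 0.00214 (0.159 with an estimated correlation)). Messages of the mitochondrial genome, fixed as a list that tracks RNA quality, moved with them: 0 of 8 genes rose and 7 fell (0 and 8 adjusted over the list alone). This list had a median log2FC of -1.41 and camera adjusted p = 1.92e-09 (0.132 with an estimated correlation). For mt-Co1 the level was 17340 ± 1997 against 58700 ± 9987, log2FC -1.75, adjusted p = 0.00183. Mitochondrial reads made up 3.09% (2.89% to 3.32%) of a VHL-deficient day 11 library and 9.13% (8.13% to 10.01%) of a WT one. The 3 measured nuclear long RNAs, the other RNA-quality list, had a median log2FC of 0.75 with 0 called (2 rose adjusted over the list alone, camera adjusted p = 0.164).

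**Figure D3:**
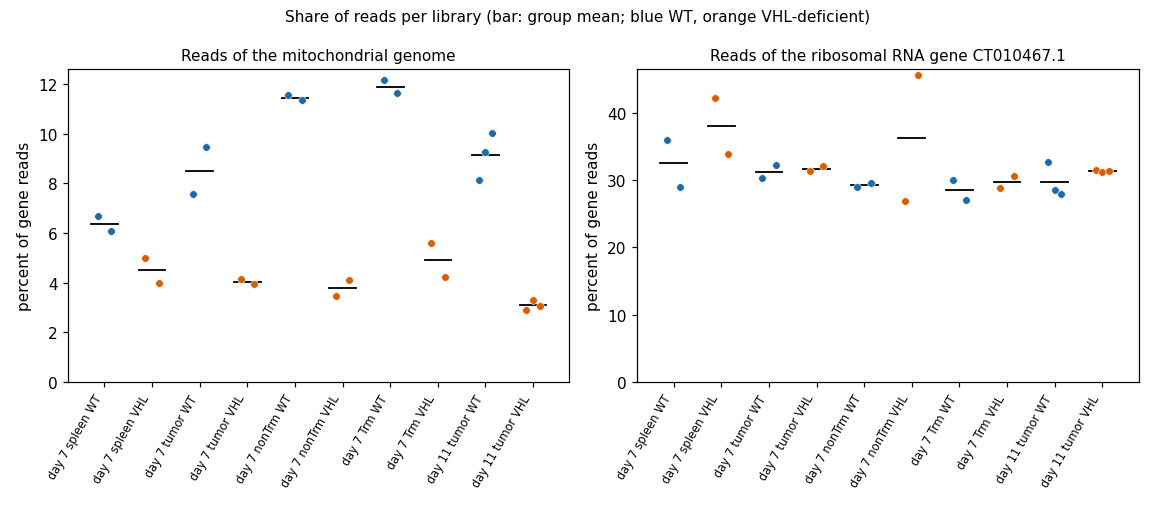
Percent of gene reads in each library that belong to the mitochondrial genome (left) and to the ribosomal RNA gene CT010467.1 (right), with 1 point per library and a bar at each group mean. The mitochondrial share is lower in each VHL-deficient group than in the WT group beside it, with 3.09% against 9.13% in day 11 tumor.

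Camera called no other metabolic list at day 11. Fatty acid oxidation had 0 of 15 genes higher and 1 lower, Acadm (125 against 227, log2FC -0.85), in both adjustments, and camera adjusted p = 0.164. None of the 16 cholesterol synthesis genes was called in either adjustment (camera adjusted p = 0.449). In amino acid transport and stress response, 1 of 17 genes rose and 3 fell (1 and 3 adjusted over the list alone). The serine and one-carbon enzymes Mthfd2 (310.3 against 833, log2FC -1.40), Phgdh (311 against 657, log2FC -1.06) and Psat1 (433 against 868, log2FC -1.02) fell, and Trib3 rose (78.4 against 23.2, log2FC 1.68). Camera gave the list an adjusted p = 0.144. The unfolded protein response had 0 of 14 genes called in either adjustment (camera adjusted p = 0.612).

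Genes of tissue residency, which mark T cells that stay in tissues, lay higher in VHL-deficient day 11 cells. In that list, 9 of 32 genes rose and 0 fell (11 and 0 adjusted over the list alone). Together they had a median log2FC of 0.48 and camera adjusted p = 8.52e-04 (0.132 with an estimated correlation). Itgae, which encodes the CD103 integrin chain that binds E-cadherin (mm10 chromosome 11, 73090583 to 73147446), rose (129 ± 59.8 against 9.74 ± 5.16, log2FC 3.63, adjusted p = 3.06e-04). So did Cdh1, E-cadherin itself (296 ± 50.6 against 22.03 ± 35.8, log2FC 5.40, adjusted p = 0.00294), Rgs1 (8491 against 3369, log2FC 1.33), the integrin Itga1 (464 against 186, log2FC 1.45) and the chemokine receptor Cxcr6 (11280 against 5627, log2FC 1.00). Cd69 had 3618 ± 543 against 2454 ± 909, log2FC 0.61, adjusted p = 0.460. Itgae also counts among the TGF-beta response genes, of which 3 of 13 genes rose and 0 fell (3 and 0 adjusted over the list alone). The set had a median log2FC of 0.58 and camera adjusted p = 0.00138 (0.207 with an estimated correlation). Circulating memory genes did not move as a set (camera adjusted p = 0.460): 1 of 23 genes rose and 3 fell (1 and 3 adjusted over the list alone). Ly6c2 (1097 against 3504, log2FC -1.67), the transcription factor Eomes (2.94 against 44.9, log2FC -3.66) and Klrg1 (3.60 against 39.3, log2FC -3.08) fell and Ripor2 rose (511 against 298, log2FC 0.80).

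Among effector genes at day 11, perforin Prf1 rose (18370 ± 5979 against 7850 ± 4907, log2FC 1.35, adjusted p = 0.0388) with Il2 (116 against 9.04, log2FC 3.99) and Gzmg (1968 against 86.2, log2FC 4.78). For the cytotoxic list, 3 of 20 genes rose and 0 fell (5 and 0 adjusted over the list alone), and camera gave an adjusted p = 0.130. Granzyme B and interferon gamma were not called. Gzmb had 61120 ± 14390 against 26690 ± 12650, log2FC 1.27, adjusted p = 0.0826, and Ifng had log2FC -0.27, adjusted p = 0.736. Of the inhibitory receptors and exhaustion genes, 3 of 18 genes rose and 0 fell (3 and 1 adjusted over the list alone). They were Cd101 (437 against 78.5, log2FC 2.47), Vsir (2883 against 1274, log2FC 1.18) and Havcr2, which encodes TIM-3 (2263 against 1064, log2FC 1.13). That list had a median log2FC of -0.08, a mean of 0.15 and a camera adjusted p = 0.460. The checkpoint receptor Pdcd1 had log2FC -0.11, adjusted p = 0.878. Costimulatory receptors included 4 that rose of 13 and 0 that fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.0734). Tnfsf9 (280.3 against 35.3, log2FC 3.05), Slamf7 (1280 against 538, log2FC 1.24) and Tnfrsf9 (12380 against 6342, log2FC 0.98) were among them. In the stem-like list, 1 of 14 genes rose and 1 fell (1 and 2 adjusted over the list alone), with camera adjusted p = 0.562. The survival gene Bcl2 rose (1507 against 655, log2FC 1.21), Myb fell (27.3 against 138, log2FC -2.39), and Tcf7 had log2FC -1.02, adjusted p = 0.243. Effector transcription factors were split, with Prdm1 (1.68) and Runx3 (0.81) higher and Eomes and Irf8 (-0.97) lower, 2 each way of 13 in both adjustments. Their median of 0.11 and mean of -0.06 differ in sign, and the camera adjusted p was 0.857. Chemokines and their receptors gave 4 that rose and 1 that fell of 18 (8 and 1 adjusted over the list alone, median log2FC 0.87, camera adjusted p = 0.00907 (0.109 with an estimated correlation)). The cytokine Csf2 (1054 against 142, log2FC 3.12) and Cxcr4 (124 against 25.8, log2FC 2.26) were higher and Cxcr3 lower (178 against 575, log2FC -1.66). Immediate early genes had 3 that rose of 17 and 0 that fell (4 and 0 adjusted over the list alone, median log2FC 0.77, camera adjusted p = 0.00867 (0.280 with an estimated correlation)). They were Ier3, Btg2 and Jun, by 1.56, 1.12 and 0.99 log2 units.

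Proliferation genes fell together in day 11 tumor: 0 of 25 genes rose and 17 fell (0 and 20 adjusted over the list alone). The list had a median log2FC of -1.90 and camera adjusted p = 2.25e-17 (0.132 with an estimated correlation). The S-phase enzyme gene Tyms fell (151 ± 16.9 against 563 ± 8.11, log2FC -1.90, adjusted p = 2.99e-04), as did Top2a (712 against 2322, log2FC -1.70), Ccne1 (107 against 428, log2FC -2.09) and the proliferation marker Mki67 (356 ± 56.4 against 1270 ± 104, log2FC -1.84, adjusted p = 2.74e-05). Among type I interferon response genes, 0 of 18 genes rose and 5 fell (0 and 7 adjusted over the list alone). The members had a median log2FC of -0.94 and camera adjusted p = 1.51e-05 (0.200 with an estimated correlation). Oasl2 (6.65 against 34.4, log2FC -2.16), Usp18 (24.4 against 91.8, log2FC -2.03), Bst2 (119.5 against 265, log2FC -1.15) and Ifit3 (9.61 against 39.5, log2FC -1.81) were among those that fell.

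Among markers of other cell types at day 11, the genes called for genotype came from the dendritic-cell, B-cell and NK-cell lists. No marker of melanoma (0 of 4 measured), macrophages and monocytes (0 of 8), neutrophils (0 of 1), CD4 T cells (0 of 6), fibroblasts and endothelium (0 of 2) or erythroid cells (0 of 1) was called. Adjusted over the list alone, 1 rose among neutrophil markers (Mmp9), and 1 rose and 1 fell among CD4 T-cell markers. The camera adjusted p-values were 0.258 for melanoma, 0.495 for macrophages, 0.826 for CD4 T cells and 0.826 for fibroblasts. Lists with 1 measured gene were not tested. Neutrophil granule genes under the filter were read in WT replicate 2, such as Elane with 277 scaled counts there and at most 3.84 in any other library. Of the 12 T-cell markers of the cells' own type, 0 were called in either adjustment (camera adjusted p = 0.857). Dendritic-cell markers split, with H2-Ab1 and Xcr1 (194 against 61.6, log2FC 1.67) higher and H2-Aa (5.62 against 79.6, log2FC -3.46) and H2-Eb1 (6.41 against 53.3, log2FC -2.75) lower (2 and 2 of 8, 2 and 3 adjusted over the list alone, camera adjusted p = 0.992). Both partner genes were highest in WT replicates 1 and 2, with 115 and 93.5 for H2-Aa against 30.3 in replicate 3. Ighm, from the B-cell list, fell (74.8 against 427, log2FC -2.57; 1 of 2 in both adjustments, camera adjusted p = 0.374). NK-cell markers had 0 that rose and 2 that fell of 5, Eomes and Klrb1f (0 and 3 adjusted over the list alone, median log2FC -2.41, camera adjusted p = 0.00339 (0.132 with an estimated correlation)). The 4 measured sex-linked genes had 0 called in either adjustment (camera adjusted p = 0.495).

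In unsplit day 7 tumor the same question was asked with 2 libraries of each genotype. St6gal1 (1623 ± 66.2 against 22.6 ± 2.00, log2FC 6.11), Mgarp (746 against 11.3, log2FC 5.92), P4ha2 (769.8 ± 49.97 against 14.2 ± 3.16, log2FC 5.68, adjusted p = 2.23e-09) and H2-Ab1 (1698 against 37.6, log2FC 5.48, adjusted p = 5.04e-06) rose. Sema6d, Ppp1r3b, Bnip3 (3441 against 174, log2FC 4.32), Pygl, Egln3 (2268 against 123, log2FC 4.19) and Plcxd1 rose too. The chemokine receptor Cxcr3 fell (92.8 ± 20.3 against 578 ± 230, log2FC -2.58, adjusted p = 8.00e-04), as did Ctse, a cathepsin (82.3 against 457, log2FC -2.41), Eno3 (78.8 against 414, log2FC -2.33), Samd3 and Ly6c2 (783 ± 115 against 3364 ± 1515, log2FC -2.03, adjusted p = 0.0199). Itgae rose (142 ± 26.0 against 3.44 ± 1.78, log2FC 5.05, adjusted p = 1.34e-04). Vegfa had 0 reads in both WT libraries and 51.6 scaled counts in VHL-deficient ones, at least 10-fold higher against a floor of 3 reads per library. Of 14327 genes, 241 rose and 32 fell, 273 together. That count was 94 without VHL-deficient replicate 1, 117 without VHL-deficient replicate 2, 131 without WT replicate 2 and 424 without VHL-deficient nonTrm replicate 2.

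Both HIF lists rose in unsplit day 7 tumor. For glycolysis and glucose uptake, 13 of 21 genes rose and 0 fell (19 and 0 adjusted over the list alone). As a set, these had a median log2FC of 1.67 and camera adjusted p = 4.19e-20 (0.00109 with an estimated correlation). Slc2a1 had 1398 against 302, log2FC 2.21, Pgk1 4362 against 1388, log2FC 1.67 and Pdk1 1509 ± 97.2 against 404 ± 145, log2FC 1.95, adjusted p = 0.0488, while Ldha had log2FC 0.89, adjusted p = 0.269. For other HIF targets, 14 of 26 genes rose and 0 fell (21 and 0 adjusted over the list alone). This list had a median log2FC of 1.74 and camera adjusted p = 6.83e-30 (4.67e-05 with an estimated correlation). Chemokine genes, with Cxcr4 higher (124 against 16.7, log2FC 2.92) and Cxcr3 lower, had 1 each way of 18 (10 and 1 adjusted over the list alone, median log2FC 1.27, camera adjusted p = 9.88e-04 (0.0249 with an estimated correlation)). Residency genes followed the day 11 direction: 4 of 32 genes rose and 0 fell (8 and 0 adjusted over the list alone), with median log2FC 0.56, camera adjusted p = 1.12e-04 (0.0850 with an estimated correlation). Qpct (81.3 against 6.71, log2FC 3.46), Itga1 (312 against 76.0, log2FC 2.11) and Rgs1 (9533 against 3617, log2FC 1.46) rose beside Itgae. The proliferation list had 0 of 25 genes called in either adjustment and median log2FC -0.93, camera adjusted p = 1.07e-05 (0.426 with an estimated correlation). Mitochondrial messages fell again (0 of 8 genes rose and 2 fell (0 and 8 adjusted over the list alone), median log2FC -1.26, camera adjusted p = 1.11e-07 (0.203 with an estimated correlation)), with 4.03% of reads in VHL-deficient and 8.51% in WT libraries. Oxidative phosphorylation had 0 of 31 genes called in either adjustment and median log2FC -0.59, camera adjusted p = 2.90e-07 (0.391 with an estimated correlation). Prf1 rose (16500 ± 1.48 against 4602 ± 150.4, log2FC 1.84, adjusted p = 0.0468). Gzmb (log2FC 1.72, adjusted p = 0.116), Ifng (log2FC 0.10, adjusted p = 0.949), Pdcd1 (log2FC 0.15, adjusted p = 0.896), Tcf7 (log2FC -1.62, adjusted p = 0.238), Hif1a (log2FC -0.69, adjusted p = 0.292) and Cd69 (log2FC 0.19, adjusted p = 0.908) were not called.

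VHL-deficient cells of day 7 spleen, outside the tumor, also carried high HIF-target levels (n = 2 each). P4ha2 had 241 ± 2.61 scaled counts against 0 reads in both WT libraries, at least 65.9-fold higher. The metallothionein gene Mt2 had 55.4 against 0 reads, at least 15.2-fold higher. H2-Ab1 (486 ± 68.5 against 3.31 ± 3.20, log2FC 7.04, adjusted p = 8.44e-08), Mgarp (224 against 2.78, log2FC 6.45) and the aldolase Aldoc (1256 ± 72.8 against 19.2 ± 18.2, log2FC 6.34, adjusted p = 3.02e-08) rose as well. Ccr7, which guides T cells to lymph nodes, fell (103 ± 15.8 against 609 ± 16.6, log2FC -2.56, adjusted p = 0.00559) with Crtam (11.3 against 83.5, log2FC -3.30), Samd3 (22.9 against 193, log2FC -3.05), the interferon-induced gene Ifit2 (23.3 against 143, log2FC -2.87) and Arl4d (49.2 against 283, log2FC -2.52). In total 350 genes rose and 105 fell, 455 together. It was 80 with only the groups compared in the fit. The count was 231 without VHL-deficient replicate 1, 264 without WT replicate 1 and 279 without WT replicate 2.

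Glycolytic HIF targets stood out in spleen: 15 of 21 genes rose and 0 fell (18 and 0 adjusted over the list alone). Together they had a median log2FC of 2.45 and camera adjusted p = 1.21e-31 (1.12e-04 with an estimated correlation). Slc16a3 had 1350 ± 69.8 against 25.8 ± 6.83, log2FC 5.68, adjusted p = 1.25e-10, the triose phosphate isomerase Tpi1 6554 against 332, log2FC 4.31, Pgk1 1538 against 149.5, log2FC 3.36, Ldha 13910 ± 720.4 against 2729 ± 339, log2FC 2.35, adjusted p = 2.86e-04 and Slc2a1 855 against 141, log2FC 2.59. For other HIF targets, 16 of 26 genes rose and 0 fell (19 and 0 adjusted over the list alone), with median log2FC 2.07, camera adjusted p = 3.55e-30 (4.68e-05 with an estimated correlation). Vegfa was at least 5.10-fold higher, with 18.7 scaled counts against 0 reads. Gzmb (5654 ± 260.5 against 1482 ± 347, log2FC 1.95, adjusted p = 0.0467) and Gzmc (496 against 8.72, log2FC 5.68) rose. So did the receptors Ctla4 (1278 ± 119 against 197 ± 81.5, log2FC 2.75, adjusted p = 7.24e-06), Lag3 (388 against 184, log2FC 1.06), Tnfrsf9 (268 against 34.2, log2FC 3.02) and Slamf7 (2897 against 583, log2FC 2.30). Inhibitory receptors had 4 that rose and 1 that fell of 18 (6 and 1 adjusted over the list alone, median log2FC 0.50, camera adjusted p = 0.0299 (0.154 with an estimated correlation)). Costimulatory receptors had 5 and 1 of 13 (5 and 1 adjusted over the list alone, median log2FC 0.50, camera adjusted p = 0.0176 (0.148 with an estimated correlation)). In the residency list, 8 of 32 genes rose and 1 fell (12 and 2 adjusted over the list alone), with median log2FC 0.62, camera adjusted p = 0.00413 (0.154 with an estimated correlation). Among them were Bhlhe40 (3083 against 753, log2FC 2.03), the T-cell receptor response gene Nr4a1 (65.4 against 14.1, log2FC 2.14) and Cish. Circulating memory genes had 0 that rose and 2 that fell of 23, Sidt1 and Ccr7 (0 and 3 adjusted over the list alone, median log2FC -0.48, camera adjusted p = 0.00312 (0.195 with an estimated correlation)). Interferon response genes had 0 and 2 of 18 (0 and 12 adjusted over the list alone, median log2FC -1.32, camera adjusted p = 1.89e-10 (0.110 with an estimated correlation)). Ifit3 was lower (27.2 against 134, log2FC -2.37). Cholesterol synthesis genes had 0 of 16 called in either adjustment with median log2FC -0.93, camera adjusted p = 0.00103 (0.248 with an estimated correlation). Mitochondrial messages in spleen had 0 of 8 called in either adjustment and a camera adjusted p = 0.381, with 4.50% of reads against 6.37%. Pdk1 (log2FC 1.199, adjusted p = 0.280), Hif1a (log2FC -0.58, adjusted p = 0.402), Ifng (log2FC -0.24, adjusted p = 0.910), Tcf7 (log2FC -1.96, adjusted p = 0.101), Itgae (435 ± 261 against 142 ± 57.8, log2FC 1.52, adjusted p = 0.328), Cd69 (log2FC 1.02, adjusted p = 0.484) and Pdcd1 (log2FC 0.00, adjusted p = 1.00) were not called.

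Whether the genotype effect differed between unsplit tumor and spleen at day 7 was tested as an interaction. Slc16a3 and Tpi1, a pair of glycolytic HIF targets, differed less by genotype in tumor, where Slc16a3 had 4982 against 729 and Tpi1 14630 against 4596, than in spleen. Their interaction log2 values were -2.92 (adjusted p = 0.0148) and -2.62 (adjusted p = 0.0360). The inhibitory receptor gene Ctla4, at 5175 against 3735 in tumor and 1278 against 197 in spleen, had -2.30 (adjusted p = 0.047). Bnip3l, a mitophagy receptor, went the other way with 1.53 (adjusted p = 0.0469), at 1363 against 287 in tumor and 635 against 388 in spleen. Nfil3, Tubb6 and Prelid2 had genotype fold changes of 0.56, 0.76 and 2.37 log2 units in tumor and 3.49, 3.42 and 5.27 in spleen. In all, 10 genes were called, 3 with a positive and 7 with a negative interaction, and 1377 had an unadjusted p under 0.05. The remaining 3, named after their values were seen, were Nid1, Tmem119 and D630039A03Rik. The count was 0 without VHL-deficient tumor replicate 1 or 2, 1 without WT tumor replicate 2, 2 without WT spleen replicate 2, 3 without VHL-deficient spleen replicate 1, 16 without VHL-deficient spleen replicate 2 and 17 without VHL-deficient nonTrm replicate 2. With voom in place of the trend fit it was 2, and without trend 1. The glycolytic HIF list had 0 genes with a positive and 2 with a negative interaction of 21 (1 and 10 adjusted over the list alone, median log2FC -0.69, camera adjusted p = 6.22e-06 (0.186 with an estimated correlation)).

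Within the Trm-sorted cells of day 7 tumor (n = 2 each), loss of VHL raised the HIF targets P4ha2 (766 ± 106 against 11.6 ± 1.14, log2FC 5.92, adjusted p = 9.91e-10) and Egln3 (3208 against 151, log2FC 4.40) together with Mgarp (968 ± 191 against 14.99 ± 3.64, log2FC 5.93, adjusted p = 1.30e-06), Rgs11 (1752 against 32.0, log2FC 5.79), Igf1r (607 against 12.3, log2FC 5.44) and Pygl (1784 against 65.5, log2FC 4.75). It lowered Eno3 (14.7 ± 4.35 against 299.7 ± 65.4, log2FC -4.27, adjusted p = 2.41e-07) and the mitotic genes Plk1 (58.6 against 424, log2FC -3.28), Ube2c (149 against 857, log2FC -3.07), Cks1b (93.2 against 561, log2FC -2.92) and Birc5 (142 against 830, log2FC -2.90). Itgae rose (1068 ± 983 against 26.1 ± 15.8, log2FC 5.04, adjusted p = 1.02e-04), with the replicates far apart. In total 726 genes rose and 720 fell, 1446 together. It was 234 without VHL-deficient Trm replicate 2, 411 without WT Trm replicate 1 and 2358 without VHL-deficient nonTrm replicate 2.

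In Trm cells the proliferation list fell: 0 of 25 genes rose and 18 fell (0 and 19 adjusted over the list alone). The set had a median log2FC of -2.14 and camera adjusted p = 1.94e-13 (0.157 with an estimated correlation). Mki67 had 422 ± 71.6 against 1784 ± 59.4, log2FC -2.08, adjusted p = 1.02e-04. Glycolytic HIF targets rose (13 of 21 genes rose and 0 fell (18 and 0 adjusted over the list alone), median log2FC 1.53, camera adjusted p = 1.16e-12 (0.00891 with an estimated correlation)). So did other HIF targets (19 of 26 genes rose and 0 fell (24 and 0 adjusted over the list alone), median log2FC 2.46, camera adjusted p = 7.16e-21 (2.98e-04 with an estimated correlation)), with Slc2a1 at 1812 against 280.4, log2FC 2.72 and Vegfa at 61.8 against 2.45, log2FC 4.18. Oxidative phosphorylation fell (0 of 31 genes rose and 9 fell (0 and 16 adjusted over the list alone), median log2FC -0.85, camera adjusted p = 1.88e-09 (0.277 with an estimated correlation)), with Atp5b at 4140 against 11330, log2FC -1.48 and Cyc1 at 472 against 1303, log2FC -1.45. Mitochondrial messages fell beside it (0 of 8 genes rose and 6 fell (0 and 8 adjusted over the list alone), median log2FC -1.63, camera adjusted p = 1.53e-07 (0.157 with an estimated correlation)), with 4.90% of reads against 11.9%. The nuclear long RNA Neat1 rose (1180 ± 701 against 287 ± 161, log2FC 2.02, adjusted p = 0.00694), 1 of 3 in its list (2 adjusted over the list alone). Mthfd2 (256 against 1105, log2FC -2.31), Phgdh (267 against 1059, log2FC -2.01) and Asns (67.8 against 259.6, log2FC -2.33) were among the amino acid genes, of which 0 of 17 genes rose and 5 fell (1 and 8 adjusted over the list alone). The list had a median log2FC of -0.78 and camera adjusted p = 2.39e-04 (0.157 with an estimated correlation). For tissue residency, 9 of 32 genes rose and 2 fell (13 and 3 adjusted over the list alone). The members had a median log2FC of 0.92 and camera adjusted p = 1.64e-04 (0.133 with an estimated correlation). Itga1 (523 against 96.7, log2FC 2.49) and Cxcr6 (20430 against 8000, log2FC 1.39) rose, and Xcl1 (228 against 1390, log2FC -2.86) and Crtam (109 against 691, log2FC -2.77) fell. TGF-beta response genes included Ski (1.21) and Ldlrad4 (2.53), and 5 of 13 genes rose and 0 fell (7 and 0 adjusted over the list alone). As a set, these had a median log2FC of 1.17 and camera adjusted p = 1.64e-04 (0.157 with an estimated correlation). Ctla4 (12160 ± 714 against 4960 ± 280.1, log2FC 1.29, adjusted p = 0.0105) and Ccr2 (6399 ± 2660 against 1099 ± 656, log2FC 2.62, adjusted p = 0.00521) rose. Gzmb (log2FC 0.70, adjusted p = 0.425), Ifng (log2FC -1.10, adjusted p = 0.158), Pdcd1 (log2FC 0.25, adjusted p = 0.732), Tcf7 (log2FC -0.16, adjusted p = 0.893), Hif1a (log2FC -0.85, adjusted p = 0.0642), Ldha (log2FC 0.61, adjusted p = 0.290) and Cd69 (log2FC 1.24, adjusted p = 0.168) were not called.

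Among nonTrm cells (n = 2 each), St6gal1 (685 ± 468 against 9.09 ± 9.49, log2FC 6.32, adjusted p = 3.32e-06), Igf1r (763 against 16.2, log2FC 5.99), Mgarp (895 against 15.1, log2FC 5.73), P4ha2 (504 ± 110.5 against 9.60 ± 3.46, log2FC 5.60, adjusted p = 2.93e-09) and H2-Ab1 (2761 ± 1937 against 59.4 ± 6.44, log2FC 5.32) rose. The stanniocalcin gene Stc2, a HIF target, stood at 549 against 2.10, log2FC 7.44. The kinetochore gene Nuf2 (25.3 against 146, log2FC -2.73), Cptp (18.1 against 120.3, log2FC -2.71), Mns1 (24.9 against 133, log2FC -2.42), Cdk5rap1 (26.6 against 131, log2FC -2.31) and the asparagine synthetase Asns (30.0 against 136, log2FC -2.14) fell. Itgae had 17.1 scaled counts against 0 reads in both WT libraries, at least 5.85-fold higher (adjusted p = 0.00119). In total 236 genes rose and 96 fell, 332 together. With only the groups compared in the fit limma with trend called 0 (2199 at an unadjusted p under 0.05 and 287 by voom with all libraries), and with library weights 55. The count was 131 without WT nonTrm replicate 2, 207 without WT nonTrm replicate 1, and 1998 without VHL-deficient nonTrm replicate 1, which leaves replicate 2, the library with the highest ribosomal RNA share, alone in its group.

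HIF targets rose in nonTrm cells too (glycolysis 12 of 21 genes rose and 0 fell (19 and 1 adjusted over the list alone), median log2FC 1.51, camera adjusted p = 1.41e-16 (0.00264 with an estimated correlation)). Other targets rose as well (18 of 26 genes rose and 0 fell (22 and 0 adjusted over the list alone), median log2FC 2.10, camera adjusted p = 7.71e-29 (5.64e-05 with an estimated correlation)). Slc2a1 had 1354 ± 650 against 315 ± 33.7, log2FC 2.02, Pgk1 3083 against 867, log2FC 1.81 and Vegfa 104 against 3.07, log2FC 4.67. Amino acid genes fell, with Psat1 (142 against 527, log2FC -2.02) and Mthfd2 (164 against 547, log2FC -1.76) among 17 of which 0 rose and 4 fell (0 and 7 adjusted over the list alone, median log2FC -0.60, camera adjusted p = 1.74e-04 (0.165 with an estimated correlation)). Proliferation had 0 and 1 of 25, Mki67 (209 ± 49.1 against 526 ± 219.9, log2FC -1.28, adjusted p = 0.0157; 0 and 13 adjusted over the list alone, median log2FC -1.28, camera adjusted p = 1.64e-09 (0.303 with an estimated correlation)). Mitochondrial messages had 0 and 2 of 8 (0 and 5 adjusted over the list alone, median log2FC -0.999, camera adjusted p = 4.81e-06 (0.244 with an estimated correlation)), with 3.77% of reads against 11.4%. The TCA cycle list had 0 and 1 of 16, Idh3a (-1.15; 0 and 5 adjusted over the list alone, median log2FC -0.56, camera adjusted p = 5.86e-05 (0.0961 with an estimated correlation)). Immediate early genes had 1 and 0 of 17, Jund (108 against 23.7, log2FC 2.15; 6 and 0 adjusted over the list alone, median log2FC 1.06, camera adjusted p = 5.86e-05 (0.165 with an estimated correlation)). Chemokine genes had 2 and 0 of 18, Ccl4 (5629 against 1366, log2FC 2.08) and Ccl1 (367 against 34.6, log2FC 3.75; 2 and 1 adjusted over the list alone, median log2FC 1.24, camera adjusted p = 0.00526 (0.0672 with an estimated correlation)). Pdk1 (log2FC 1.12, adjusted p = 0.287), Ldha (log2FC 1.34, adjusted p = 0.0528), Hif1a (log2FC -0.90, adjusted p = 0.112), Gzmb (log2FC 1.08, adjusted p = 0.340), Ifng (log2FC 0.27, adjusted p = 0.870), Pdcd1 (log2FC -0.32, adjusted p = 0.789), Tcf7 (log2FC -1.39, adjusted p = 0.278) and Cd69 (log2FC 0.45, adjusted p = 0.785) were not called.

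**Figure D4:**
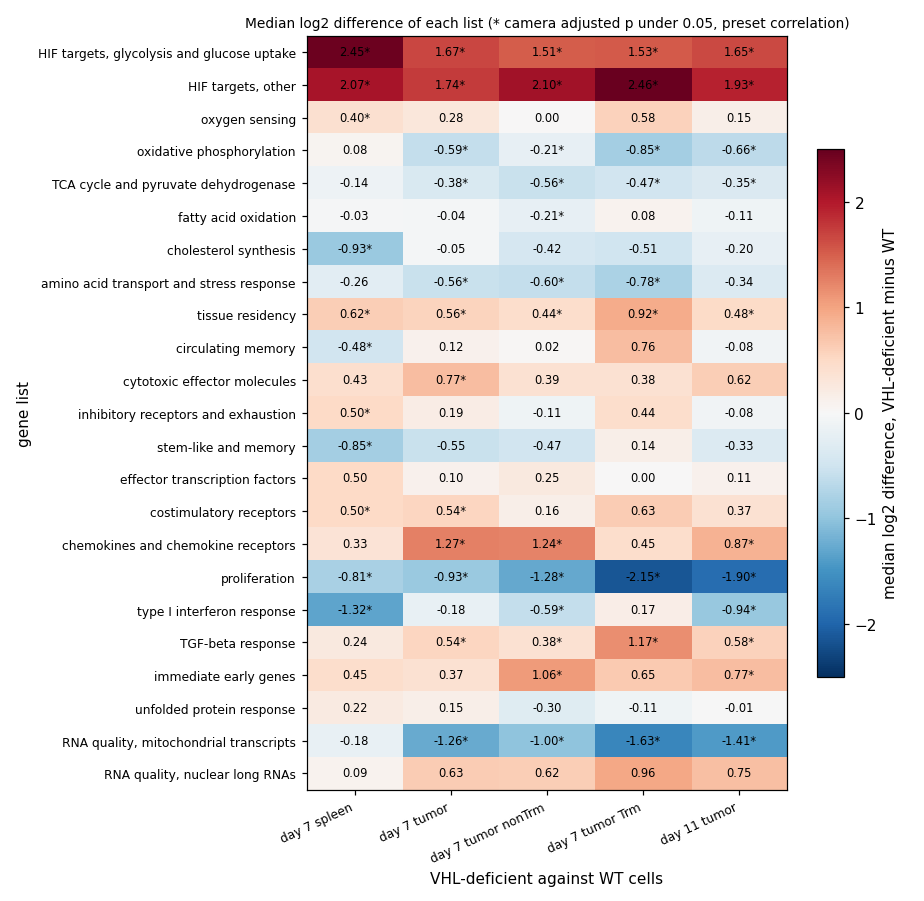
Median log2 difference, VHL-deficient minus WT, of each functional and RNA-quality gene list (rows) in the 5 genotype comparisons (columns), with an asterisk where camera with its preset correlation gave an adjusted p under 0.05. Both HIF lists lie between 1.51 and 2.46 in all 5 columns, and with the chemokine list of unsplit day 7 tumor theirs are the calls that hold with an estimated correlation.

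Markers of other cell types were also called in the day 7 genotype comparisons. In unsplit tumor Cd4 rose (23.2 scaled counts against 1 read, ratio interval 5.25 to 1240), as did Xcr1 (199 against 69.4, log2FC 1.51). The macrophage and monocyte marker Fcgr3 rose in spleen (18.7 scaled counts against 2 reads, ratio interval 3.82 to 130.1) and in nonTrm cells (50.2 against 2.63, log2FC 4.33). In Trm cells Xcr1 rose (433 against 76.4, log2FC 2.48) and H2-Eb1 fell (3.90 against 51.7, log2FC -3.25), as did Eomes (2 reads against 17.8 scaled counts, ratio interval 5.66 to 186). Ighm fell in all 4, by -2.38 in unsplit tumor, -1.80 in spleen, -1.81 in Trm and -2.08 in nonTrm cells.

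Across the 5 genotype comparisons, 90 genes were called in each, 85 higher and 5 lower. The 5 lower ones were Vhl, Ctse, Art2b, Tnip3 and Ighm. The genotype fold changes were compared between the 10 pairs of comparisons by correlation across the 14327 genes, which are not independent replicates. Day 11 tumor and Trm cells had Pearson r = 0.713 (Spearman rho = 0.691), day 11 and unsplit day 7 tumor 0.664 (0.631). The lowest pair was spleen with Trm cells at 0.265 (0.114). Of the genes called in both comparisons of a pair, 232 were shared by day 11 and unsplit day 7 tumor and 644 by day 11 tumor and Trm cells, and 0 of either had opposite signs. Day 11 tumor and spleen shared 204, of which 2 had opposite signs.

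Trm and nonTrm cells were compared among WT cells of day 7 tumor (n = 2 each). Genes called higher in Trm cells included Rrm2 (3416 ± 132 against 704 ± 427, log2FC 2.42, adjusted p = 0.0481) and Tyms (874 ± 222 against 223 ± 124, log2FC 2.06, adjusted p = 0.0191), which supply deoxynucleotides, Top2a (3122 ± 722 against 756 ± 420.3, log2FC 2.14, adjusted p = 0.0216), the DNA repair gene Ung (202 against 43.0, log2FC 2.52), Pclaf, Tk1 and the tubulins Tuba1b (3187 against 655, log2FC 2.32) and Tubb5. The enkephalin precursor Penk rose too (281 ± 70.9 against 32.0 ± 4.77, log2FC 3.08, adjusted p = 0.0300). Genes called lower included the interferon-induced Ifit1 (224 ± 113 against 1582 ± 113, log2FC -2.91, adjusted p = 0.0303) and Irf7 (355 ± 182 against 1318 ± 182, log2FC -1.98, adjusted p = 0.0315), Rtp4 (329.8 against 1151, log2FC -2.22), Samhd1 (1934 against 6972, log2FC -1.85), Ifi208, Slfn5, Slfn1, Ifit1bl1, Tcp11l2 and H2-T24. Itgae, at 142 in WT spleen, had 26.1 scaled counts in Trm cells and 0 reads in both nonTrm libraries (at least 8.93-fold, adjusted p = 0.00894). No other residency gene was called.

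By list, proliferation had 4 that rose and 0 that fell of 25 (19 and 0 adjusted over the list alone, median log2FC 1.84, camera adjusted p = 3.96e-18 (0.276 with an estimated correlation)). The interferon response had 0 and 3 of 18 (0 and 13 adjusted over the list alone, median log2FC -1.43, camera adjusted p = 6.41e-16 (0.0809 with an estimated correlation)). Circulating memory genes had 0 of 23 called (0 and 6 adjusted over the list alone, median log2FC -0.74, camera adjusted p = 4.27e-04 (0.276 with an estimated correlation)). Stem-like genes had 0 of 14 called (0 and 2 adjusted over the list alone, median log2FC -0.60, camera adjusted p = 0.00164 (0.646 with an estimated correlation)). Of the other genes fixed for Trm against nonTrm, Cd69 (2810 ± 406 against 6547 ± 5391, log2FC -0.93, adjusted p = 0.585), Cxcr6 (log2FC -0.61, adjusted p = 0.460), Klf2 (log2FC -0.77, adjusted p = 0.645), S1pr1 (log2FC -1.71, adjusted p = 0.144) and Klrg1 (log2FC -0.81, adjusted p = 0.812) were not called. In total 29 genes rose and 14 fell, 43 together. Limma called 0 with only the groups compared in the fit and 1 without trend (1629 at an unadjusted p under 0.05 and 161 by voom with all libraries). This count was 0 without WT nonTrm replicate 2, 1 without WT Trm replicate 2, 24 without WT Trm replicate 1, 141 without WT nonTrm replicate 1 and 218 without VHL-deficient nonTrm replicate 2.

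Between VHL-deficient Trm and nonTrm cells, Itgae was the only gene called, with 1068 ± 983 against 17.1 ± 0.996, log2FC 5.49, adjusted p = 0.00135 (n = 2 each), and 1257 genes had an unadjusted p under 0.05. The limma trend fit called 0 without VHL-deficient Trm replicate 2 and 2543 without VHL-deficient nonTrm replicate 1, which leaves replicate 2 alone in its group. Voom called 0 with all libraries, and limma 10 with no low filter. Cd69 (log2FC -0.14, adjusted p = 0.954), Cxcr6 (log2FC 0.63, adjusted p = 0.572), Klf2 (log2FC -0.81, adjusted p = 0.661), S1pr1 (log2FC -0.63, adjusted p = 0.719) and Klrg1 (log2FC -2.61, adjusted p = 0.524) were not called. Proliferation had 0 of 25 genes called (3 and 0 adjusted over the list alone, median log2FC 1.02, camera adjusted p = 8.70e-07 (0.753 with an estimated correlation)). The interferon response had 0 of 18 (0 and 3 adjusted over the list alone, median log2FC -0.86, camera adjusted p = 4.12e-06 (0.420 with an estimated correlation)). The interaction of genotype with subset had 0 genes called by limma with trend, 1156 at an unadjusted p under 0.05 and 0 by voom. It called 1494 without VHL-deficient nonTrm replicate 1 and 3 without WT nonTrm replicate 1.

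Unsplit tumor and spleen cells of day 7 were compared within each genotype. In WT cells (n = 2 each), S1pr1, whose receptor lets T cells leave tissues, fell in tumor (52.6 ± 21.2 against 1367 ± 110.5, log2FC -4.73, adjusted p = 1.32e-06). So did Il7r (304 against 3736, log2FC -3.66), Sidt1, Mylip and the chemokine Ccl5 (952 against 12900, log2FC -3.77). The granzyme gene Gzmc (4568 ± 1126 against 8.72 ± 2.49, log2FC 8.88, adjusted p = 5.76e-07) and the stress-induced factor Atf3 (1142 against 2.10, log2FC 8.94) rose. Rgs16 had 4697 scaled counts in tumor against 2 reads in spleen, a ratio with a 95% counting interval of 1072 to 32010. Spp1, osteopontin, had 1677 against 2 reads (329 to 9827). Il1r2 was at least 131-fold higher, with 479 scaled counts against 0 reads. Inhibitory receptors rose (12 of 18 genes rose and 1 fell (13 and 1 adjusted over the list alone), median log2FC 2.91, camera adjusted p = 3.30e-10 (0.00188 with an estimated correlation)), with Pdcd1 (3840 against 45.3, log2FC 6.37) and Lag3 (5958 against 184, log2FC 5.004). Circulating memory genes fell (2 of 23 genes rose and 16 fell (2 and 17 adjusted over the list alone), median log2FC -2.43, camera adjusted p = 3.30e-10 (0.0156 with an estimated correlation)). Tcf7, a factor of memory and stem-like cells, had 132 against 1308, log2FC -3.30. Proliferation rose (24 of 25 genes rose and 0 fell (25 and 0 adjusted over the list alone), median log2FC 3.09, camera adjusted p = 5.62e-13 (0.124 with an estimated correlation)). Cytotoxic molecules rose too (14 of 20 genes rose and 0 fell (16 and 0 adjusted over the list alone), median log2FC 2.19, camera adjusted p = 6.58e-08 (0.0724 with an estimated correlation)). Both HIF lists were higher in WT tumor cells: glycolysis 16 of 21 genes rose and 0 fell (16 and 0 adjusted over the list alone), with median log2FC 2.23, camera adjusted p = 1.54e-11 (0.0123 with an estimated correlation). For other targets, 13 of 26 genes rose and 0 fell (16 and 0 adjusted over the list alone). This list had a median log2FC of 1.75 and camera adjusted p = 9.32e-06 (0.0292 with an estimated correlation). Hif1a rose (2889 against 462, log2FC 2.60) and Itgae fell (3.44 against 142, log2FC -5.01). Of 14327 genes, 1889 rose and 1190 fell, 3079 together. The total was 1486 without WT tumor replicate 2, 1633 without WT spleen replicate 2 and 1881 without WT spleen replicate 1.

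In VHL-deficient cells the tumor again held more Spp1 (6376 scaled counts against 0 reads in spleen, at least 1391-fold higher), Rgs16 (5180 against 1 read, ratio interval 1582 to 348300), the chemokine Ccl3 (3522 ± 314 against 3.69 ± 5.22, log2FC 10.25), Gzmf (1844 against 2 reads, ratio interval 424 to 12650) and Gzmd (635 against 0 reads, at least 138-fold higher). S1pr1 (48.9 ± 28.9 against 1603 ± 57.2, log2FC -5.14, adjusted p = 5.55e-07), Rasgrp2 (43.1 against 947, log2FC -4.44), Lpar6 (79.3 against 1446, log2FC -4.22), Pik3ip1 and Abcg1 fell. Inhibitory receptors (12 of 18 genes rose and 1 fell (14 and 1 adjusted over the list alone), median log2FC 2.24, camera adjusted p = 5.48e-12 (7.46e-04 with an estimated correlation)) and chemokines (12 of 18 genes rose and 2 fell (13 and 2 adjusted over the list alone), median log2FC 3.18, camera adjusted p = 6.76e-07 (0.00239 with an estimated correlation)) lay higher in tumor. The same held for cytotoxic molecules (14 of 20 genes rose and 0 fell (15 and 2 adjusted over the list alone), median log2FC 2.95, camera adjusted p = 1.07e-08 (0.0447 with an estimated correlation)) and residency genes (15 of 32 genes rose and 1 fell (19 and 2 adjusted over the list alone), median log2FC 1.38, camera adjusted p = 6.76e-07 (0.0241 with an estimated correlation)). Circulating memory genes lay lower (2 of 23 genes rose and 16 fell (2 and 16 adjusted over the list alone), median log2FC -1.95, camera adjusted p = 2.38e-08 (0.0241 with an estimated correlation)). HIF targets were higher in tumor than in spleen even without VHL, with 12 of 21 glycolytic targets that rose and 0 that fell (16 and 0 adjusted over the list alone, median log2FC 1.12, camera adjusted p = 2.73e-07 (0.0276 with an estimated correlation)). Of the 26 others, 15 rose and 0 fell (17 and 1 adjusted over the list alone, median log2FC 1.36, camera adjusted p = 6.42e-06 (0.0241 with an estimated correlation)). Proliferation had 24 and 0 of 25 (25 and 0 adjusted over the list alone, median log2FC 2.92, camera adjusted p = 6.78e-15 (0.102 with an estimated correlation)). In total 1430 genes rose and 783 fell, 2213 together. It was 876 without VHL-deficient tumor replicate 1, 981 without VHL-deficient spleen replicate 1 and 1274 without VHL-deficient tumor replicate 2.

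Day 11 and day 7 tumor cells were set side by side within each genotype. The days lie in different columns of the plate, so day and position cannot be told apart. Limma with trend called 0 genes in WT cells (484 at an unadjusted p under 0.05, 0 by voom, and 4 without WT day 7 replicate 1). It called 0 in VHL-deficient cells (633 at an unadjusted p under 0.05, 0 by voom). In VHL-deficient cells that count was 71 with only the groups compared in the fit, 95 with library weights and 4 with no low filter, and in WT cells it was 13 with no low filter and 2 without trend. These comparisons of 3 against 2 libraries were not simulated. In simulated data of the genotype comparison in unsplit day 7 tumor, 2 against 2, the test recovered 29% of 2-fold and 92% of 4-fold changes, and 11 of 136 calls (8.09%) were false. The changed genes were drawn only from those at or above the median level, and all groups were given the same spread. Recovery among genes of lower level was not simulated. Dendritic-cell markers in WT cells had 0 of 8 called (5 and 0 adjusted over the list alone, median log2FC 1.81, camera adjusted p = 4.60e-06 (0.0384 with an estimated correlation)). Chemokine genes had 0 of 18 called in either adjustment (median log2FC 0.50, camera adjusted p = 0.00260 (0.0384 with an estimated correlation)). In VHL-deficient cells, proliferation genes had 0 of 25 called (0 and 10 adjusted over the list alone, median log2FC -1.28, camera adjusted p = 3.49e-19 (0.213 with an estimated correlation)). Interferon response genes had 0 of 18 called (0 and 6 adjusted over the list alone, median log2FC -0.82, camera adjusted p = 9.42e-10 (0.213 with an estimated correlation)). For the interaction of genotype with day, limma with trend called 0 genes, with 268 at an unadjusted p under 0.05 and 0 by voom.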

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

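The tests in this part on rescaled counts, nuclear RNAs, depth, antigen-presenting cells, the single library and the Trm sort were chosen after the result was seen; the test on genes near H2-Ab1 was planned.

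For some genes and lists the genotype effect differed between tissues, subsets or days by a test of the difference. Between unsplit tumor and spleen, interaction log2 values were -2.92 for Slc16a3, -2.93 for Nfil3, -2.67 for Tubb6 and -2.62 for Tpi1. They were -2.66 for D630039A03Rik, -2.91 for Prelid2, -2.30 for Ctla4 and 1.53 for Bnip3l. Nid1 had 6.54 and Tmem119 7.07, but neither met the naming rule on level and overlap. No read floor was applied to either, and few reads could give values of that size. Adjusted p-values of these genes ran from 0.0148 to 0.047. By list, median interactions there are given with the camera adjusted p at an estimated correlation. Medians were -0.69 for glycolytic HIF targets (0.186), -0.69 for oxidative phosphorylation (0.732), 0.66 for cholesterol synthesis (0.703) and 0.95 for chemokines (0.186). The interferon response had 1.18, mitochondrial transcripts -1.08 and sex-linked genes 1.49 (0.586 each). With subset the medians were -0.75 for oxidative phosphorylation, -0.91 for proliferation and 0.78 for the interferon response. Each had adjusted p = 0.728 with an estimated correlation. With day the medians were -0.98 for proliferation, -0.70 for the interferon response and -1.90 for dendritic-cell markers. Their adjusted p-values with an estimated correlation were 0.531, 0.531 and 0.357. None of these list calls, made with the preset correlation, held with an estimated one. The count of tissue interaction genes, 10, was 0 to 16 with 1 library of the comparison left out (0 without VHL-deficient tumor replicate 1 or 2), 2 by voom, 1 without trend and 4 with the replicate block. By limma with trend 0 genes were called for subset and 0 for day (1156 and 268 at an unadjusted p under 0.05, 0 and 0 by voom).

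Mitochondrial transcripts lay lower in VHL-deficient cells in the 4 tumor genotype comparisons. Ribosomal and mitochondrial reads that crowd out others would not explain this: after rescaling to the remaining reads the day 11 median was -1.43, and depth would not either, since the VHL-deficient library had more reads in only 6 of 9 day 11 pairs, so total reads overlapped. A difference in RNA quality stays open as a candidate explanation, because nuclear long RNAs, which gain when cytoplasmic RNA is lost, had a median difference of 0.62 or more in each of the 4 comparisons. That list has 3 measured genes, and Malat1, the most abundant, was nearly level in day 11 (7380 against 6915, log2FC 0.10) and unsplit day 7 tumor (5306 against 5022, log2FC 0.08). An effect of the genotype itself stays open beside it, untested.

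H2-Ab1 was higher in all 5 VHL-deficient groups, and its interactions with tissue, subset and day were not called. Antigen-presenting cells in the sort would bring Cd74, H2-Aa and H2-Eb1 at like levels, but their mean difference was at most 1.35% of the H2-Ab1 difference in any comparison. The partners did not move alike: in unsplit day 7 tumor Cd74 was 86.2 against 20.9 and H2-Aa 5.63 against 14.7, and in day 11 tumor they were 68.8 against 108 and 5.62 against 79.6, while the macrophage and monocyte marker Fcgr3 was called higher in spleen and nonTrm cells, at 18.7 and 50.2 scaled counts in VHL-deficient cells. Within 2 Mb of H2-Ab1, 11 of 135 genes (8.15%) were called at day 11, against 6.94% of all (Fisher exact p = 0.607). This would miss a segment of another strain that changed few genes. Reads shared with other class II genes were not tested, and an effect of the genotype stays open.

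Between VHL-deficient Trm and nonTrm cells 1 gene was called, and 43 in WT cells. The lowest VHL-deficient Trm library had 20.96 times the Itgae of the highest nonTrm library, but Itgae is the 1 gene called, so this cannot exclude a sort that separated the subsets poorly. Poor RNA in VHL-deficient nonTrm replicate 2 cannot be told apart from a small difference: without that library 1 gene was called again, but with 1 library left in the group, while the WT count rose from 43 to 218 (0 without WT nonTrm replicate 2, 1 without WT Trm replicate 2, 24 without WT Trm replicate 1, 141 without WT nonTrm replicate 1). Without VHL-deficient nonTrm replicate 1, 2543 genes were called, and without Trm replicate 2 limma with trend called 0. With all libraries 1257 genes had an unadjusted p under 0.05, and voom called 0.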

How the results depend on the processing

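The alternatives listed above as added were chosen after seeing the data. Of the 14 gene counts, all 14 stayed within 1.5 times under further TMM scaling, a pseudocount of 0.5 and recomputed size factors, 13 with a mean of at least 50 or without ribosomal and mitochondrial genes, 12 with a pseudocount of 5 or a replicate block, 11 without trend, 10 with voom, 9 without VHL-deficient nonTrm replicate 2, 8 without the low filter or with library weights and 5 with only the groups compared. Day 11 genotype calls, 984, became 604 with no low filter, 2825 with only the groups compared, 2953 with library weights and 1549 without VHL-deficient nonTrm replicate 2. Unsplit day 7 tumor, 273, became 116 (only the groups compared), 410 (weights) and 424 (without that library), and spleen, 455, became 80 (only the groups compared) and 270 (voom). Trm genotype calls, 1446, became 896 with no filter, 667 with only the groups compared and 2358 without that library, and nonTrm calls, 332, became 0 and 55 with only the groups compared and with weights. WT Trm against nonTrm, 43, became 67 (mean of at least 50), 1 (no trend), 74 (pseudocount 5), 16 (replicate block), 0 (only the groups compared), 161 (voom), 218 (without that library) and 26 (without ribosomal and mitochondrial genes). The 1 gene of VHL-deficient Trm against nonTrm became 10 with no filter and 0 with only the groups compared, weights or voom. Tumor against spleen became 1126 in WT cells with only the groups compared and 3494 in VHL-deficient cells with weights. Day counts of 0 became 13 (no filter) and 2 (no trend) in WT cells, and 4 (no filter), 71 (only the groups compared) and 95 (weights) in VHL-deficient cells. The 10 tissue interaction calls became 16 (no filter), 1 (no trend), 5 (pseudocount 5), 4 (replicate block), 2 (voom) and 17 (without that library). Of 448 list tests, 126 were called with the preset correlation, 26 with an estimated one and 105 by fry. The median correlation of genotype effects, 0.499, was 0.609 for genes above the median level and 0.413 by Spearman. Without VHL-deficient nonTrm replicate 2 the oxidative phosphorylation and mitochondrial lists reversed sign between VHL-deficient Trm and nonTrm cells, with adjusted p = 0.0219 for each. Leaving out 1 library of the groups compared gave 419 to 683 for day 11 genotype, 94 to 331 for unsplit day 7 tumor, 231 to 337 for spleen, 234 to 1525 for Trm, 131 to 1998 for nonTrm, 0 to 141 and 0 to 2543 for Trm against nonTrm in WT and VHL-deficient cells, 1486 to 2745 and 876 to 1543 for tumor against spleen, 0 to 4 and 0 to 0 for day, and 0 to 1494, 0 to 16 and 0 to 0 for the interactions with subset, tissue and day. Fits with fewer groups or libraries have fewer residual degrees of freedom, yet some of their counts rose, as at day 11 from 984 to 2825. The cause of the changes was not tested. The paired replicate block gave 826 calls at day 11, 227 in unsplit day 7 tumor, 389 in spleen, 1209 in Trm and 271 in nonTrm cells, 2770 and 2009 for tumor against spleen; the correlation of deviations between libraries of the same number ran from 0.029 to 0.271 in the genotype comparisons and from -0.181 to -0.011 in the others, so whether the numbers pair libraries is not settled. Scaling without ribosomal and mitochondrial genes took the median log2 fold change of all genes from 0.04 to -0.13 in WT Trm against nonTrm, from 0.08 and 0.06 to -0.26 and -0.14 in tumor against spleen, from 0.01 to 0.18 in the subset interaction, from -0.03 to 0.10 in the tissue interaction, and from 0.04 and 0.02 to -0.10 in the spleen and nonTrm genotype comparisons. Of 3432 values of named genes, 3066 stayed called or stayed not called, 334 lost a call, 32 gained one and 0 reversed. In simulated data of 3 against 3 libraries, 57% of 2-fold and 100% of 4-fold changes were recovered, and 8 of 177 calls (4.52%) were false. There too, the changed genes came only from those at or above the median level, with the same spread in all groups.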

Other observations

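The tests below of day 11 splits, genes near Vhl and Trm share were planned.

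Unsplit tumor cells differed from spleen in lists not described above. Of immediate early genes in WT cells, 12 of 17 genes rose and 1 fell (12 and 1 adjusted over the list alone), with median log2FC 2.04, camera adjusted p = 3.68e-05 (0.0826 with an estimated correlation), among them Nr4a1 (3195 against 14.1, log2FC 7.73). The effector factors Irf8 (2816 against 30.0, log2FC 6.57) and Irf4 (908 against 31.5, log2FC 4.77) rose too. Of amino acid genes, 8 of 17 genes rose and 0 fell (11 and 0 adjusted over the list alone), with median log2FC 1.51, camera adjusted p = 7.00e-05 (0.0873 with an estimated correlation), among them Atf4 (1686 against 444, log2FC 1.93) and Phgdh (1116 against 262, log2FC 2.04). In VHL-deficient cells 7 of 16 cholesterol synthesis genes rose and 0 fell (8 and 0 adjusted over the list alone, median log2FC 1.52, camera adjusted p = 1.68e-04 (0.145 with an estimated correlation)).

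In day 11 WT replicate 2, a library of the day 11 genotype comparison, granulocyte genes reached 277 scaled counts for Elane, 198 for Mpo, 149 for S100a9, 104 for S100a8, 91.2 for Camp and 42.8 for Ngp, while the highest value of any of the 6 in the other 21 libraries was 9.84.

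The 6 day 11 libraries give 10 splits into 3 and 3. The real split called 984 genes (419 to 683 with 1 left out), the others 0 by limma with trend. The others mix genotypes, whose effect widens their spread, so their 0 decides nothing. A share of splits under 0.1 cannot be reached.

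A segment of another strain carried with the Vhl allele could change genes nearby. Within 10 Mb of Vhl, 6 of 113 tested genes (5.31%) were called at day 11, against 6.94% of all (Fisher exact p = 0.708). This would miss a segment that changed few genes.

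A larger share of Trm cells among unsplit VHL-deficient tumor cells could have given their genotype effect. Over 272 called genes, across genes, that effect correlated with the WT Trm against nonTrm difference at r = 0.214, and with the genotype effect within Trm and nonTrm cells at 0.898 and 0.841, which argues against the share as the whole cause.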
